A study of Oryza sativa with 36 samples.

How the data were processed

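The series holds 36 samples of rice (Oryza sativa, cultivar Nipponbare) seedlings grown in hydroponic culture to an age of 15 days, with 12 h of light at 26 °C and darkness at 22 °C. Shoots and roots came from wild type, from rice carrying FTO (an RNA demethylase of animals that removes N6-methyladenosine, m6A) and from rice carrying FTOmut, a form of the enzyme without demethylase activity. Per the labels, 12 libraries are RNA-seq of RNA depleted of ribosomal RNA, with ERCC spike-in RNA added to total RNA before that depletion, and the other 24 are input and immunoprecipitated libraries of m6A-seq from poly(A) RNA. The labels also give polyA RNA as the molecule of the RNA-seq samples, which conflicts with that depletion; the text follows the protocol. Each genotype and tissue has 2 replicates of each kind. The labels do not state that replicates came from separate cultures, so every p-value measures only the spread between these samples.

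Per the labels, the authors trimmed reads with cutadapt 1.15, aligned them with HISAT2 2.1.0 and counted them with featureCounts of Subread 1.6.4. The deposited gene and repeat tables, 1 of each per tissue, hold expected counts: whole reads plus fractions where a read was shared between places. No normalization had been applied by the authors. Each gene table lists 55801 genes and 92 ERCC transcripts, and each repeat table lists 283220 repeat copies. The deposited tables also give the length of each row in bp, which is of an other unit than the counts and was used only for counts per kb. For m6A-seq, the authors deposited a list of peaks in genes and a list of peaks in repeats for each replicate, and the labels' descriptions name MeTPeak as the peak caller. In these deposited lists the fold is a ratio of immunoprecipitate over input, the peak FDR is on a log10 scale, and the score is a p-value. The caller's settings and the genome build are not given in the sources used here, so positions are printed as the lists give them.

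Expected counts were rounded to whole numbers. Within each tissue, all 6 RNA-seq libraries were fitted together with edgeR 4.0.16 under R 4.3.3, with 1 mean per genotype. Genes with low counts were removed by edgeR's filter by expression, libraries were scaled by TMM, and each pair of genotypes was compared with the robust quasi-likelihood F test, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. A gene is called higher or lower in the text when it passed that test. Repeat copies were tested likewise with the library sizes and TMM factors of the genes, so that a change of a repeat is a change relative to genes. Repeat families, taken as the leading letters of the repeat names, were tested on summed counts. The difference between the FTO effect in root and in shoot was tested as a contrast over all 12 libraries. Levels per library are log2 CPM with a prior count of 0.5. SE is the standard error of the fitted log2 fold change, and SD is over the 2 replicates.

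The gene identifiers of the tables carry no names. Lists of genes for pathways, tissue markers and regulators were fixed before the data were examined, as 92 pairs of a symbol and an identifier from the published rice nomenclature. Of these, 91 identifiers are in the gene tables. The reference gene table used here is of another assembly and matched 0 of the identifiers, so each pair was checked only by chromosome and order: 60 symbols occur once in the reference on the chromosome that the identifier gives, in the same order along it. Genes are printed by name only where this check passed, while list tests use all members. The parts of the lists that rested on descriptions of genes could not be filled, and lists with no member are not reported. Named genes follow a rule also fixed before the data were examined. For FTO against wild type it takes the 10 largest changes each way among called genes with a mean log2 CPM (counts scaled to library size) of at least 1 and no overlap between the libraries of both genotypes, for the other comparisons 5 each way, plus up to 4 called members of each list. Because names were limited as described, the rule could take only listed genes. Where fewer than 10 genes passed, it takes the 10 with the smallest p, which the text gives as values. The 2 loci on chromosome 9 described below were chosen after their values were seen.

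Lists with at least 5 tested members were tested with camera of limma 3.58.1, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera asks whether the members of a list moved more than other genes did. It was repeated with a correlation estimated from the data, and fry was run as a test of each list alone. Peaks were compared with bedtools 2.31.1. A peak was replicated when peaks of both replicates overlapped by at least 1 bp on the same strand, and absent from another genotype when neither of its replicates had an overlapping peak. Shares of peaks carry a 95% Wilson interval, which covers counting error only. Numbers of peaks per library were compared by an exact permutation test, two-sided, with genotypes permuted within each tissue. It has 225 arrangements for FTO against both other genotypes and 36 for FTO against wild type. The same exact test served for gene counts per spike-in count. Genes with peaks lost or gained were tested in the RNA-seq libraries with camera, and set beside 10000 random sets matched on expression.

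Alternatives tried were RLE factors, no filter on low counts, DESeq2 1.42.0, a term for the replicate number, scaling by ERCC counts, only the 4 libraries of both genotypes compared, each library left out in turn, and for repeats the factors of their own table. For peaks they were an FDR of at most 0.01, a reciprocal overlap of 50% and genes of at least 10 CPM. Leaving out FTOmut replicate 2 from comparisons that do not involve it, leaving out the 2 chromosome 9 loci, a peak fold of at least 10, and fry for the genes with peaks were chosen after seeing the data. Where a library was left out, the remaining one is assumed to vary like the other groups.

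The test was tested on simulated counts with the mean levels, library sizes and fitted spread of each tissue and 200 genes changed. In shoot it recovered 0% of genes changed 2-fold, 14% of those changed 4-fold and 80% of those changed 8-fold. In root the shares were 30%, 82% and 80%. The correlation between the FTO and FTOmut effects was compared with 20 simulations of unchanged groups, because both effects share the wild-type libraries. Peak positions within transcripts and sequence motifs were not analysed here. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the remaining steps.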

Results

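The RNA-seq part measured gene and repeat transcripts in shoots and roots of 15-day-old wild-type, FTO and FTOmut rice seedlings, with 2 libraries in each of the 6 groups. The m6A-seq part gave 12 lists of peaks in genes and as many in repeats, 1 per replicate. Gene counts per library, in units of 1e+06, were 13.0 and 13.9 in wild-type shoot, 17.6 and 17.9 in FTO shoot, and 16.4 and 17.6 in FTOmut shoot. In root they were 13.4 and 16.0 in wild type, 16.2 and 17.1 in FTO, and 16.6 and 16.4 in FTOmut. FTO against wild type compares rice with and without FTO, so it does not isolate the demethylase activity. FTOmut carries the protein without that activity.

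Counts assigned to genes were higher relative to the ERCC spike-in in FTO libraries than in those of the other genotypes. In shoot, FTO libraries had 290.1 ± 28.0 gene counts per ERCC count (SD, n = 2), against 70.6 ± 10.98 in wild type and 76.4 ± 22.8 in FTOmut. In root the values were 23.0 ± 0.475 in FTO, 11.5 ± 1.22 in wild type and 11.001 ± 1.66 in FTOmut (SD, n = 2). FTO exceeded the mean of the other genotypes 3.996-fold in shoot and 2.05-fold in root (exact permutation p = 0.00444, the smallest of 225 arrangements). Against wild type alone the exact permutation p was 0.0556 over 36 arrangements, the smallest that this two-sided test can give. Part of this excess lay in 2 neighbouring loci on chromosome 9, LOC_Os09g01000 and LOC_Os09g00999. What these loci encode was not analysed here and remnants of ribosomal RNA were not ruled out, so gene counts are not a measure of messenger RNA alone. They held 64.2 ± 0.858% of gene counts in FTO shoot (SD, n = 2), 27.7 ± 9.47% in wild type and 16.4 ± 3.03% in FTOmut. In root they held 22.6 ± 0.836% in FTO, 2.75 ± 0.623% in wild type and 2.76 ± 2.18% in FTOmut (SD, n = 2). LOC_Os09g01000 was higher in FTO than in wild-type root with a log2 fold change of 2.77 (SE 0.58, edgeR adjusted p = 0.0202), while LOC_Os09g00999 was not called there (4.28, adjusted p = 0.0683). Neither was called in shoot. Without both loci, gene counts per ERCC count in FTO were 1.84 times those of the other genotypes in shoot and 1.63 times in root, with the same exact permutation p = 0.00444.

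**Figure D1:**
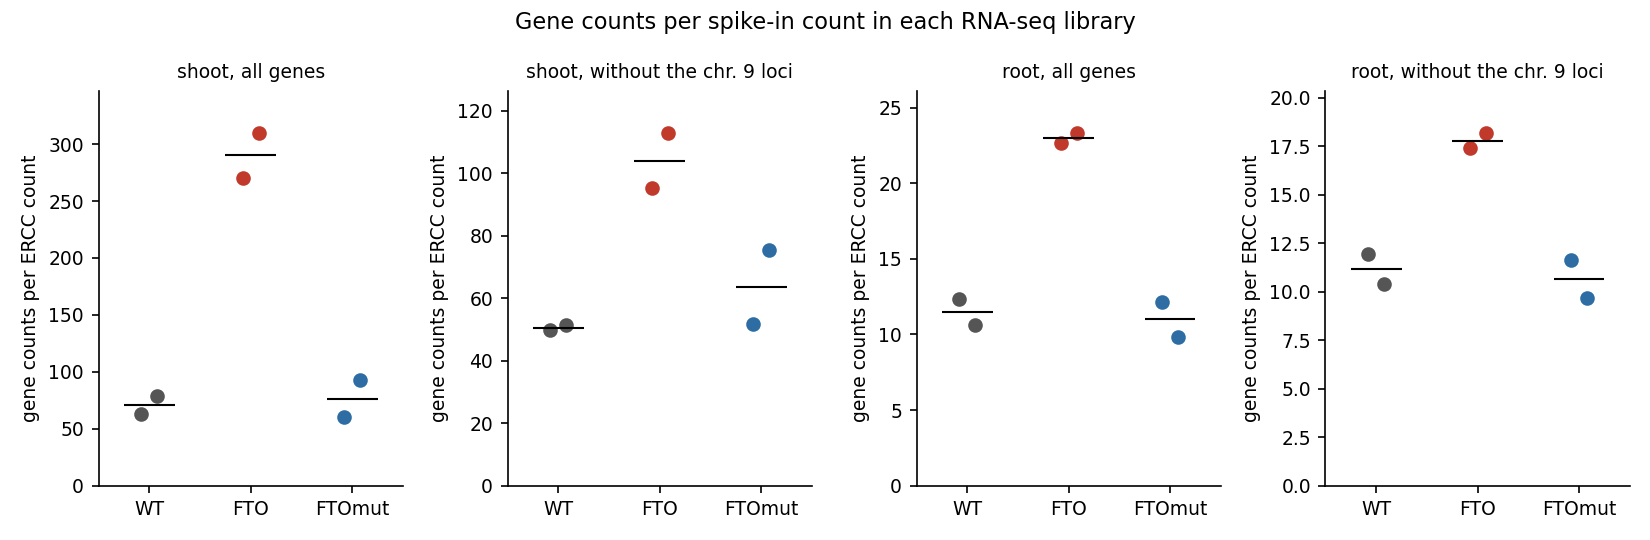
Gene counts per ERCC spike-in count (vertical axis, linear from 0) in each RNA-seq library (points) by genotype, with bars at the group means, for shoot and root, with all genes and without the 2 loci on chromosome 9 (chr. 9). The FTO libraries lie above those of wild type and FTOmut in each panel, with means of 290.1 in shoot and 23.0 in root over all genes.

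Libraries of 1 genotype were close to each other in root wild type and root FTO, with Spearman correlations across genes of 0.985 and 0.981. Genes are not independent replicates, so these values carry no test. In shoot, the wild-type libraries correlated at 0.839 with each other, while wild-type replicate 1 correlated at 0.960 and 0.961 with the FTO libraries, and wild-type replicate 2 at 0.915 with FTOmut replicate 1. FTOmut replicate 2 had 36486 genes with at least 10 counts in shoot and 46166 in root, against 21859 and 30053 in FTOmut replicate 1 and between 18065 and 28201 in the libraries of wild type and FTO.

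**Figure D2:**
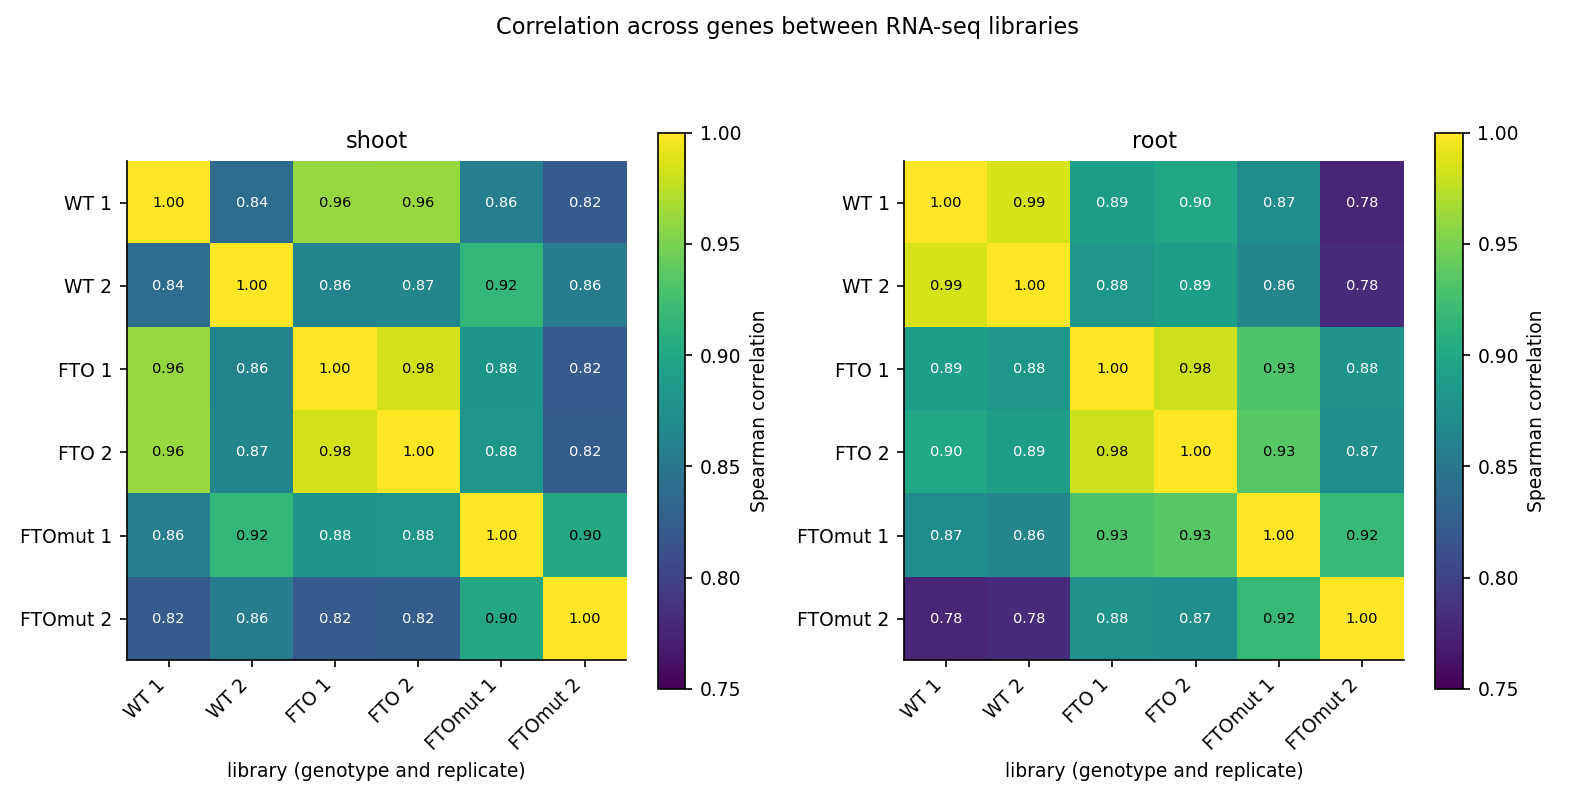
Spearman correlation across genes between each pair of RNA-seq libraries, named by genotype and replicate on both axes, in shoot and root; the colour scale runs from 0.75 to 1. In shoot the wild-type libraries correlate at 0.839 with each other, below the 0.960 of wild-type replicate 1 with an FTO library.

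In FTO roots, genes of iron acquisition fell relative to wild type. All 6 tested members of the iron uptake list were lower, with a median log2 fold change of -2.24. OsNAAT1 (LOC_Os02g20360), an aminotransferase of the synthesis of mugineic acid iron chelators, was 7.85-fold lower (log2 -2.97, SE 0.20). The nicotianamine synthase genes OsNAS1 (LOC_Os03g19427) and OsNAS2 (LOC_Os03g19420) were 4.27-fold and 3.87-fold lower. OsYSL15 (LOC_Os02g43410), a transporter of iron bound to such chelators, was 5.24-fold lower, and OsIRT1 (LOC_Os03g46470), a transporter of ferrous iron, 2.18-fold lower. Diterpenoid phytoalexin genes fell as well, with 5 of 7 members lower and a median of -1.35. Among them were CYP99A3 (LOC_Os04g09920) at -2.43, CYP99A2 (LOC_Os04g10160) at -2.04, OsKSL7 (LOC_Os02g36140) at -1.82 and OsCPS4 (LOC_Os04g09900) at -1.35. OsCPS2 (LOC_Os02g36210) and OsKSL4 (LOC_Os04g10060) were not called, at 0.19 and -0.23.

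All 5 members of the list of abscisic acid, drought and LEA genes were higher in FTO roots, with a median log2 fold change of 1.88. OsDREB1A (LOC_Os09g35030), a transcription factor gene known for its response to cold, was 20.6-fold higher (log2 4.37, SE 0.23), and OsLEA3 (LOC_Os05g46480), which encodes a late embryogenesis abundant protein, 3.66-fold higher (log2 1.87, SE 0.19). Of 8 circadian clock and flowering genes, 5 were lower and 1 was higher. The pseudoresponse regulator genes OsPRR95 (LOC_Os09g36220), OsPRR1 (LOC_Os02g40510) and OsPRR37 (LOC_Os07g49460) changed by -2.32, -1.09 and -1.08, and OsLHY (LOC_Os08g06110), a morning component of the clock, by 1.07. Between the wild-type shoot replicates OsLHY differed more than this, with a log2 CPM of 9.27 and 5.75. The sample details used here give no hour of harvest. For clock genes, time of day therefore cannot be told apart from genotype, in FTO or in FTOmut. Of 14 regulators of tillering, strigolactone and yield, 3 were higher: D10 (LOC_Os01g54270), an enzyme of strigolactone synthesis, at 2.33 (SE 0.83), GW2 (LOC_Os02g14720), a ubiquitin ligase known to limit grain width, at 1.43 (SE 0.19), and SLR1 (LOC_Os03g49990), the DELLA repressor of gibberellin signalling, at 0.86 (SE 0.20). Of 11 RNA silencing and DNA methylation genes, 5 were lower. They included OsMET1b (LOC_Os07g08500) at -1.46, OsRDR2 (LOC_Os04g39160) at -1.01, OsCMT3a (LOC_Os10g01570) at -0.89 and OsDRM2 (LOC_Os03g02010) at -0.55. The phosphate transporter gene OsPT2 (LOC_Os03g05640) was lower at -1.58, and the chlorophyll-binding protein gene Cab1R (LOC_Os09g17740) at -1.08, the only 1 of 4 photosynthesis genes called, with Cab2R (LOC_Os01g41710) at 0.19.

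In all, edgeR called 11400 of 32467 genes in FTO against wild-type root, 5296 higher and 6104 lower. Camera's adjusted p was 5.17e-07 for iron uptake, 0.000225 for phytoalexins and 1.16e-05 for abscisic acid, drought and LEA genes, each with adjusted p = 0.0994 under an estimated correlation. It was 0.0482 for clock genes (adjusted p = 0.526 with an estimated correlation), 0.0538 for RNA silencing genes and 0.144 for tillering regulators. Adjusted over the list alone, 6 iron, 5 phytoalexin, 5 abscisic acid, 6 clock, 6 silencing and 2 tillering genes passed. With ERCC scaling, which moved the median of all genes from 0.19 to 0.92, the call split 9870 higher and 2398 lower: of the named members, 4 of 5 iron and 5 of 7 phytoalexin genes were called lower, 1 phytoalexin gene higher and 2 clock genes lower, and OsIRT1, OsPRR1, OsRDR2, OsCMT3a, OsDRM2 and Cab1R were not called. The count was 7044 or 5810 without wild-type replicate 1 or 2, 4825 or 5208 without FTO replicate 1 or 2, and 18234 without FTOmut replicate 2, and OsLHY, SLR1 and OsDRM2 were not called when any 1 library of wild type or FTO was left out. Calls were also lost for D10 and OsCMT3a without wild-type replicate 1 or either FTO replicate, for GW2 without wild-type replicate 1, for OsMET1b, OsPRR1 and OsPRR37 without FTO replicate 1, for OsIRT1, Cab1R and OsRDR2 without FTO replicate 2, and for SLR1 with DESeq2 or no filter.

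**Figure D3:**
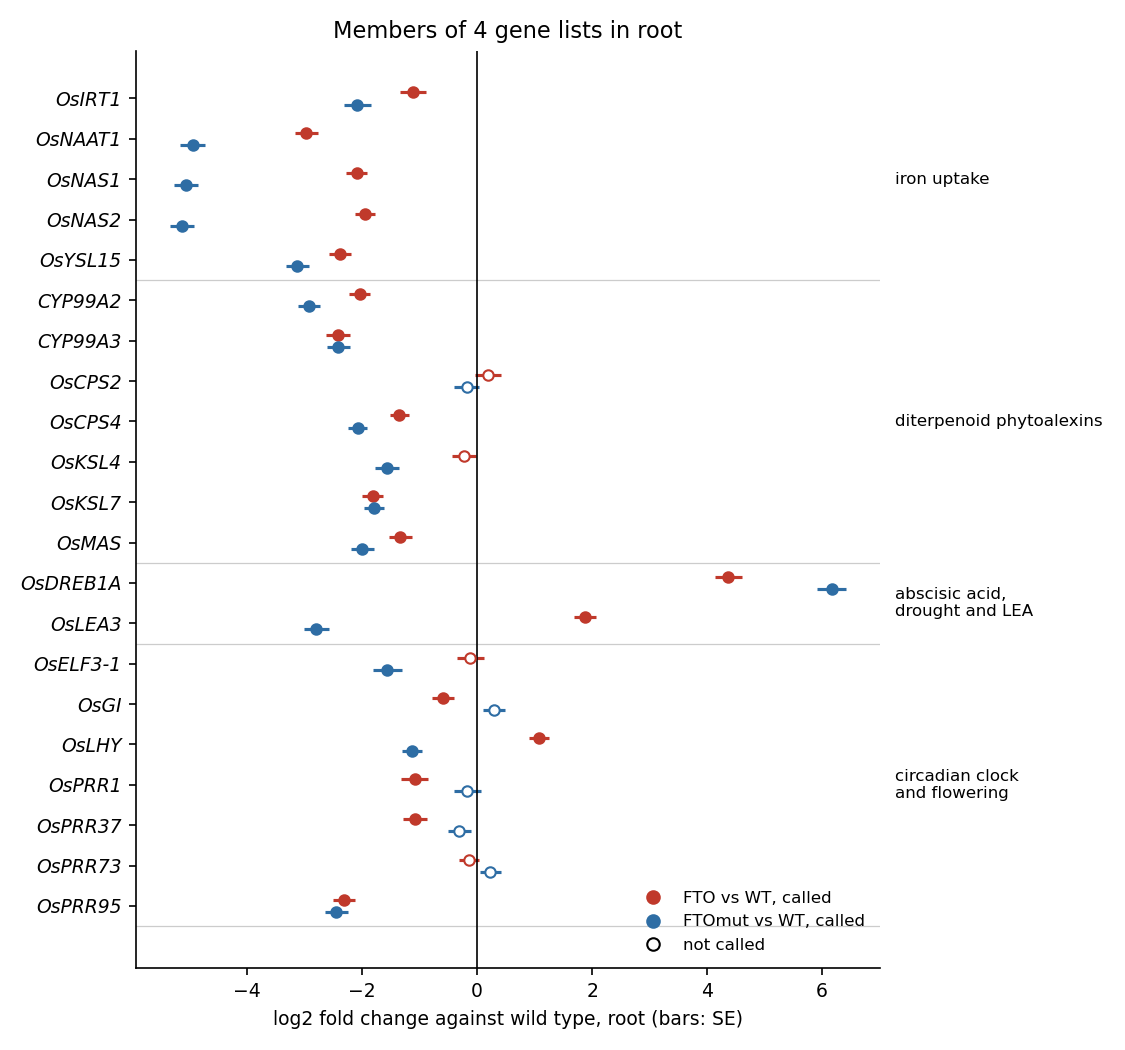
Log2 fold change against wild type in root (horizontal axis; bars, SE of the fit) for named members of 4 gene lists, in FTO (red) and FTOmut (blue); filled points passed edgeR's test at an adjusted p under 0.05 and open points did not. Iron uptake genes lie below 0 in both genotypes, from -1.12 to -2.97 in FTO and down to -5.14 in FTOmut, while OsLEA3 lies at 1.87 in FTO and -2.80 in FTOmut.

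FTOmut roots showed lower iron uptake and phytoalexin genes too. All 6 iron uptake genes were lower than in wild type, with a median log2 fold change of -4.65. OsNAS2 was 35.2-fold lower (log2 -5.14, SE 0.21), OsNAS1 33.5-fold lower and OsNAAT1 30.9-fold lower. Of the phytoalexin genes, 6 of 7 were lower with a median of -2.00, including CYP99A2 at -2.92. OsDREB1A was 71.9-fold higher (log2 6.17, SE 0.25), whereas OsLEA3 was 6.95-fold lower (log2 -2.80, SE 0.22). The chlorophyll-binding protein genes Cab2R and Cab1R, markers of green tissue, were higher by 4.17 and 2.18, and 3 of the 4 photosynthesis genes were called higher. Cab2R had a log2 CPM of 8.26 and 7.62 in FTOmut root, 3.64 and 3.96 in wild-type root and 9.58 and 9.70 in FTOmut shoot. Whether the FTOmut roots held green tissue was not tested, which limits each comparison with them. Of the tillering regulators 5 of 14 were lower, among them SD1 (LOC_Os01g66100), a gibberellin oxidase, at -2.69, IPA1 (LOC_Os08g39890), a transcription factor gene of shoot architecture, at -2.02, and the strigolactone signalling genes D3 (LOC_Os06g06050) at -1.69 and D14 (LOC_Os03g10620) at -0.93. Of 8 clock genes 4 were lower, including OsPRR95 at -2.45, OsELF3-1 (LOC_Os06g05060) at -1.56 and OsLHY at -1.14. The defence gene PBZ1 (LOC_Os12g36880) was lower at -3.19 (SE 0.61), and OsNAR2.1 (LOC_Os02g38230), a partner of nitrate transporters, was higher at 0.65.

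EdgeR called 19997 genes in FTOmut against wild-type root, 10562 higher and 9435 lower, a direction that turned under alternatives: 7425 higher and 10353 lower with DESeq2, 4906 and 7736 without wild-type replicate 1, 5131 and 7240 without replicate 2, and 8299 and 8786 without FTOmut replicate 2. Camera's adjusted p was 1.44e-06 for iron uptake and 0.000181 for phytoalexins, each with adjusted p = 0.136 under an estimated correlation, and no other list passed. Adjusted over the list alone, 6 iron, 6 phytoalexin, 4 clock, 4 tillering and 3 photosynthesis genes passed. The count was 12642 or 12371 without wild-type replicate 1 or 2 and 33822 without FTOmut replicate 1, and the call of OsNAR2.1 was lost without wild-type replicate 1 or 2, without FTOmut replicate 1, with DESeq2 and with no filter.

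Between both transgenic genotypes, iron uptake genes were higher in FTO than in FTOmut roots, all 6 of them, with a median log2 fold change of 1.72. OsNAS2 was 9.09-fold and OsNAS1 7.85-fold higher in FTO, and OsLEA3 25.4-fold higher (log2 4.67, SE 0.22). Of the tillering regulators 6 of 14 were higher, among them SD1 at 2.18, IPA1 at 2.18, GW2 at 1.93, D3 at 1.63 and D14 at 1.46. Phytoalexin genes were higher in 4 of 7 cases, with OsKSL4 at 1.34. All 4 photosynthesis genes were lower in FTO, Cab2R by -3.98 and Cab1R by -3.26, and OsDREB1A was 3.49-fold lower (log2 -1.80, SE 0.20). Among 8 clock genes, OsLHY at 2.21 and OsELF3-1 at 1.44 were higher, while OsPRR1 at -0.92 and OsGI (LOC_Os01g08700) at -0.89 were lower; under ERCC scaling 3 clock genes were called higher and 0 lower.

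EdgeR called 6576 genes between FTO and FTOmut root, 4799 higher in FTO and 1777 lower. With ERCC scaling the split widened to 10558 to 666. Without FTOmut replicate 2 and with TMM it was near even. The excess of higher genes therefore depended on that library and on the scaling, and both changes were not tried together. Camera's adjusted p was 1.08e-06 for iron uptake and 0.00045 for tillering regulators, each with adjusted p = 0.162 under an estimated correlation, and 0.0329 for phytoalexins (adjusted p = 0.237 with an estimated correlation). Adjusted over the list alone, 6 iron, 7 tillering, 4 phytoalexin, 4 photosynthesis and 5 clock genes passed. The count was 4195 with DESeq2, 11224 with ERCC scaling, 3198 or 2955 without FTO replicate 1 or 2, and 17741 without FTOmut replicate 1. ERCC scaling moved the median of all genes from -0.11 to 0.27. Without FTOmut replicate 2, 3 of the 5 named iron genes were called. OsGI lost its call without either FTO replicate, and OsPRR1 without either FTO replicate or FTOmut replicate 1.

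The FTO and FTOmut effects in root were correlated across genes. Of the called genes, 3920 were higher and 5067 lower in both, where independent lists would share 1723 and 1774. The log2 fold changes correlated across genes at 0.856, against 0.495 in simulations of unchanged groups that share the wild-type libraries. Their covariance was 2.26, against 0.166 in the simulations. In shoot the correlation was -0.284 (simulated 0.493). With 2 wild-type libraries these could not be divided between both effects, and genes are not independent replicates.

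In shoots, edgeR called no gene in any pair of genotypes, and the levels of stress and iron genes are given as values. OsLEA3 had a log2 CPM of 3.03 ± 0.09 in FTO shoot (SD, n = 2), 0.61 ± 0.37 in wild type and 0.01 ± 0.20 in FTOmut. OsDREB1A stood at 2.77 ± 0.27 in FTO, 4.33 ± 0.54 in wild type and 7.35 ± 0.03 in FTOmut (SD, n = 2). OsNAS1 was at 6.77 and 6.67 in the FTO libraries, 4.89 and -2.81 in wild type, and -2.40 and -1.76 in FTOmut. OsNAS2 was at 6.69 and 6.58 in FTO, 4.94 and -2.81 in wild type, and -1.09 and 0.24 in FTOmut. OsNAAT1 averaged 5.94 ± 0.12 in FTO, 3.94 ± 1.41 in wild type and 2.64 ± 0.40 in FTOmut (SD, n = 2). D14 and SD1 had log2 fold changes of -1.12 and -1.72 in FTOmut against wild type.

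Of 24463 genes tested in shoot, edgeR called 0 in each comparison at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 974 genes in FTO against wild type, 2294 in FTOmut against wild type and 4205 in FTO against FTOmut, and DESeq2 called 31, 394 and 1181. Camera's adjusted p for iron uptake genes was 4.02e-07 in FTO against wild type, upward with a median of 2.21 over 5 members, and 0.000697 in FTO against FTOmut. With an estimated correlation the adjusted p was 0.535 and 0.523. Adjusted over the list alone, 0 and 4 iron genes passed. The counts moved when a library was left out, where the filter also let more genes in (35928 and 35018 without wild-type replicate 1 and 2): FTO against wild type gave 3946 genes without wild-type replicate 1 and 239 without replicate 2, and FTOmut against wild type 2069 and 4302. FTO against FTOmut gave 131 and 125 without FTO replicate 1 and 2, 3779 with only the 4 libraries compared, 1024 with no filter, and 1183 with ERCC scaling, which in FTO against wild type moved the median of all genes from -0.20 to 0.87.

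The FTO effect differed between root and shoot for 1275 of 38524 genes in edgeR's test of the difference, 719 with a more positive effect in root and 556 with a more negative one. OsDREB1A had the more positive effect in root, by a log2 difference of 5.56 (SE 0.50, adjusted p = 0.000536). OsNAAT1 and OsYSL15 had the more negative effect in root, by -5.05 (SE 0.74) and -5.04 (SE 0.76); OsYSL15 had a log2 CPM of only -1.17 and -2.33 in wild-type shoot, so its size depends on few counts. RLE factors divided the genes 1097 to 371, and the replicate term 479 to 609. DESeq2 called 2691. The count was 3259 or 469 without wild-type shoot replicate 1 or 2, 320 or 332 without FTO shoot replicate 1 or 2, 282 or 240 without wild-type root replicate 1 or 2, and 332 or 327 without FTO root replicate 1 or 2.

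Counts at repeats changed in roots relative to genes. Of 22760 repeat copies tested in root, 2232 were called in FTO against wild type, 1637 higher and 595 lower. Among long terminal repeats, 1 copy each named LTR_Sb_chr_07_952 and LTR_Os_chr_05_1057 was higher by 8.56 (SE 0.39) and 8.60 (SE 0.59). These names cover 187 and 52 copies, so the values are not those of all copies. A copy named LTR_Sb_chr_07_952 was also higher in FTOmut against wild type, by 9.71. The largest fall among called copies in FTO was -7.91, in 1 of 40 copies named LTR_AC198891.2_10973, at a mean log2 CPM of only -0.42. In FTOmut against wild type 13456 copies were called, 11776 higher and 1680 lower, and 126 of 211 repeat families, 121 of them higher. Between FTO and FTOmut root 533 copies were called. Genes silent in wild-type root also held more counts in both transgenic genotypes. Their median counts per kb were 3.44 and 2.64 in FTO, 3.91 and 17.5 in FTOmut, and 0.676 and 0.995 in wild type. They were chosen as low in wild type, which by itself lowers its values. Reads that do not come from transcripts were therefore not ruled out among the higher repeat copies. No repeat family was called by edgeR in FTO against wild type or FTOmut (63 and 5 at an unadjusted p under 0.05). With the factors of the repeat table itself, FTO against wild type gave 828 copies higher and 2356 lower, and FTOmut against wild type 2956 higher and 4973 lower, with 32 families higher and 34 lower, so the prevailing direction depended on the scaling. FTO against wild type gave 12071 copies without FTOmut replicate 2 and 1010, 967, 963 or 956 without a wild-type or FTO library. FTOmut against wild type gave 1896 or 2004 without a wild-type replicate, 30359 without FTOmut replicate 1, and 9506 without FTOmut replicate 2, 7217 higher and 2289 lower, where the median of all copies fell from 2.11 to 1.05. FTO against FTOmut gave 281 without either FTO replicate, 17229 without FTOmut replicate 1 and 1658 without replicate 2. In shoot edgeR called 0 of 9778 copies in each comparison (298, 466 and 1479 at an unadjusted p under 0.05; DESeq2 called 0, 1 and 39). Leaving out 1 library gave up to 511 copies in FTO against wild type, 506 in FTOmut against wild type and 11802 in FTO against FTOmut, the last without FTOmut replicate 1, and a fit of only the 4 libraries gave 835 in FTO against FTOmut.

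The number of m6A peaks in genes did not differ detectably between FTO and the other genotypes. FTOmut against wild type was not tested. These numbers count called peaks and do not measure how much m6A a site or the RNA as a whole held. Wild-type shoot had 13452.5 ± 692 peaks (SD, n = 2), FTO shoot 14457.5 ± 383 and FTOmut shoot 14326.5 ± 326. In root there were 14416.5 ± 513 in wild type, 15107 ± 1261 in FTO and 14777 ± 109 in FTOmut (SD, n = 2). FTO exceeded the other genotypes by 539 peaks on average (exact permutation p = 0.213, adjusted 0.310 over the 16 tests of this family). Covered length was 174 kb more in FTO (exact permutation p = 0.0489, adjusted 0.199). Peaks in repeats numbered 5368.5 ± 596 in wild-type shoot, 6186.5 ± 418 in FTO and 7602 ± 1632 in FTOmut, and in root 4003 ± 175, 5215.5 ± 473 and 5822 ± 397 (SD, n = 2). FTO exceeded wild type by 1015 repeat peaks (exact permutation p = 0.0556, the smallest that this two-sided test can give, adjusted 0.199).

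**Figure D4:**
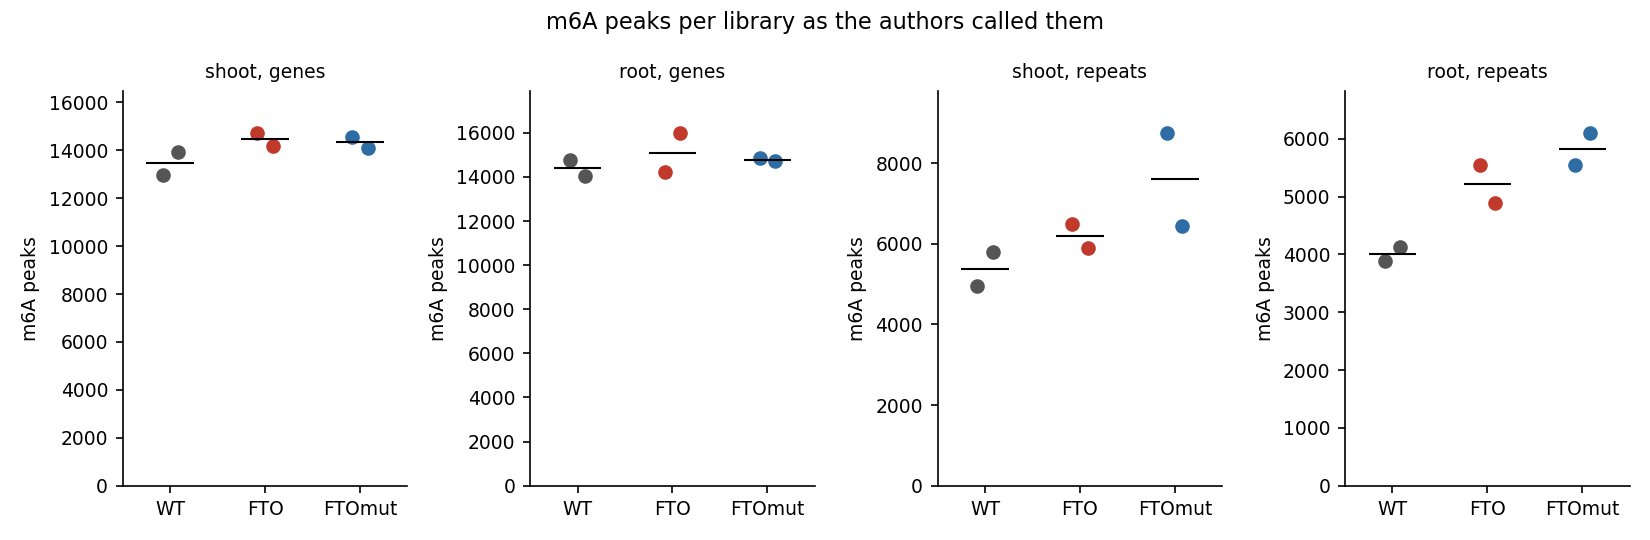
Number of m6A peaks (vertical axis, linear from 0) in each replicate (points) by genotype, with bars at the group means, for genes and repeats in shoot and root. In genes the group means run from 13452.5 in wild-type shoot to 15107 in FTO root, and in repeats from 4003 in wild-type root to 7602 in FTOmut shoot.

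Most replicated wild-type peaks were also found in FTO. In shoot 267 of 11626 replicated wild-type gene peaks, 2.30% (95% Wilson interval 2.04 to 2.59), had no overlapping peak in either FTO replicate, and in root 326 of 12280, 2.65% (2.38 to 2.95). The shares absent from FTOmut were 2.65% (2.37 to 2.96) in shoot and 4.92% (4.55 to 5.32) in root. In the other direction, 5.20% of replicated FTO peaks were absent from wild type in shoot and 4.70% in root. Of the wild-type peaks absent from FTO, 68 in shoot and 69 in root had overlapping peaks in both FTOmut replicates. These lay in 67 genes in each tissue, none of them a named gene. Peaks found in only a single FTOmut replicate were not counted, so the other peaks need not be absent from FTOmut. In repeats, 12.9% of replicated wild-type peaks in shoot and 7.78% in root were absent from FTO, and 9.27% and 11.3% from FTOmut. Conversely, 18.5% of replicated FTO repeat peaks in shoot and 20.1% in root were absent from wild type. With single replicates, the wild-type repeat peaks absent from FTO rose to 30.4 and 39.0% in shoot and 30.8 and 34.7% in root. Among single replicates of wild type and FTO, 9.10 to 19.2% of wild-type gene peaks had no counterpart. Between the wild-type replicates themselves, 10.3% of the gene peaks of replicate 1 in shoot and 16.9% in root had none in replicate 2.

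Genes with m6A peaks in wild type had a slightly lower median change in FTO roots than matched random sets. The 10760 tested genes with a replicated wild-type peak had a median log2 fold change of -0.27, against -0.12 in random sets matched on expression (camera adjusted p = 7.06e-06, or 0.426 with an estimated correlation). Fry, which tests the set alone and not against other genes, gave an adjusted p of 0.174. In FTOmut roots the same 10760 genes also moved down (camera adjusted p = 1.46e-13; 0.198 with an estimated correlation). In FTO against FTOmut root the 10760 genes moved up (adjusted p = 1.26e-07; 0.681 with an estimated correlation). The genes whose peaks were lost or gained in FTO had median log2 fold changes of -0.49 (306 genes) and 0.55 (523 genes) in FTO against wild-type root, and of -0.46 and 0.64 in FTOmut against wild-type root. Finding a peak takes reads of the gene, and in genes with at least 10 CPM the share of peaks absent fell from 2.65 to 1.33% and from 4.70 to 1.94%. These sets are thus partly chosen by the level in each genotype, and the 10760 genes by the level in wild type. Random sets were matched only on the mean level over all libraries of the tissue, which does not remove such a choice. The tests of all 3 sets therefore do not tell an effect of m6A on expression. In shoot none of the 3 sets passed in FTO against wild type, with adjusted p of 0.301, 0.301 and 0.782.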

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

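The tests of the chromosome 9 loci, of sequencing depth, of label exchanges, of FTOmut material at a log2 gap of 1, of mean counts per kb and of the 100 most abundant root-enriched genes were chosen only after the result was seen.

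The effect of FTO against wild type differed between root and shoot for 1275 genes in edgeR's test of that difference. Among iron uptake genes, the log2 difference (root minus shoot) was -5.05 for OsNAAT1 (LOC_Os02g20360, SE 0.74, adjusted p = 0.00533), -5.04 for OsYSL15 (LOC_Os02g43410, SE 0.76, adjusted p = 0.00604) and -3.12 for OsIRT1 (LOC_Os03g46470, SE 0.71, adjusted p = 0.0331). OsDREB1A (LOC_Os09g35030) had a difference of 5.56 (SE 0.50, adjusted p = 0.000536) and the clock gene OsPRR95 (LOC_Os09g36220) of -2.36 (SE 0.53, adjusted p = 0.0324). The phytoalexin gene OsCPS2 (LOC_Os02g36210) had a fitted difference of 7.68 (SE 1.58, adjusted p = 0.0256), but both FTO shoot libraries hold 0 counts of it, so this size depends on the fit and is no bound; OsYSL15 and OsIRT1 are near the floor in shoot too, with a log2 CPM of OsYSL15 of -1.17 and -2.33 in wild type and too few counts of OsIRT1 for the shoot test, so their sizes carry the same limit. The number of genes moved when a library was left out, where the filter also kept 46252 to 47200 genes against 38524, from 240 without wild-type root replicate 2 to 3259 without wild-type shoot replicate 1, and was 469 without wild-type shoot replicate 2, 282 without wild-type root replicate 1, 320 or 332 without FTO shoot replicate 1 or 2, and 332 or 327 without FTO root replicate 1 or 2.

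In shoot, wild-type replicate 2 stands apart from replicate 1, which resembles the FTO libraries, and this spread enters each shoot comparison. The clock gene OsLHY had a log2 CPM of 9.27 in wild-type replicate 1 and 9.19 and 9.08 in FTO. It stood at 5.75 in wild-type replicate 2 and 6.93 and 7.39 in FTOmut. Other clock genes differed less between wild-type replicates 1 and 2. OsPRR95 stood at 8.27 and 7.07, OsELF3-1 at 5.31 and 4.66 and OsPRR37 at 5.19 and 4.55. OsPRR73 stood at 7.52 and 7.37, OsGI at 8.22 and 8.55 and OsPRR1 at 5.29 and 5.68. The photosynthesis genes Cab1R and Cab2R were lower in replicate 2 too, at 9.49 and 7.68 and at 8.99 and 7.19. In FTOmut they stood at 9.42 and 10.10 and at 9.58 and 9.70. What lies behind the OsLHY split was not tested. Root tissue in replicate 2 was tested by genes enriched in root: their median log2 ratio of replicate 2 to 1 exceeded that of all expressed genes by 0.968, just under the 1 set before as its sign and like the FTOmut libraries at 0.988 and 0.929, which decided nothing, but the 100 most abundant root-enriched genes, which root cells would bring in proportion, gained a median of 0.649% of their root level (upper quartile 4.12%) against 8.74% over all 1409, which argues against root RNA as the whole source. An exchange of labels needs a partner out of place, but the FTO libraries correlate at 0.984 with each other and at most at 0.865 with wild-type replicate 2, and the FTOmut libraries at 0.901 with each other and at most at 0.857 with wild-type replicate 1. FTOmut material in place of wild-type replicate 2 alone needs no partner, and that library correlates at 0.915 with FTOmut replicate 1: over 387 genes set apart in FTOmut by a log2 gap of 1, chosen without the wild-type shoot libraries, its median position between FTO at 0 and FTOmut replicate 1 at 1 was 0.565 (quartiles 0.262 and 0.888), between the 0.0285 of wild-type replicate 1 and the 0.982 of FTOmut replicate 2 (quartiles 0.758 and 1.204), and a gap of 3 set before left 1 gene, at 1.197, so this cannot be told apart. Other transgenic material, a wrong label within wild type or a real difference between the seedlings may remain, none of which was tested. The m6A-seq list of gene peaks of the same number holds a peak named HygR, which no such list of FTO or FTOmut rice holds. Its fold was 4, against a median of 26 in that list.

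FTO libraries hold fewer spike-in counts per gene count in both tissues. The 2 loci on chromosome 9 explain part of it, yet without them the log2 difference of FTO to the other genotypes was still 0.709 in root and 0.88 in shoot, above the 0.4 set as the bound. Reads from genomic DNA in FTO libraries would raise counts at genes silent in wild type: the higher FTO root replicate had a median of 3.44 counts per kb there, below both FTOmut root libraries, but the shoot medians of FTO and FTOmut replicate 1 are both 0, so this test decided nothing in shoot. By mean counts per kb, the lowest FTOmut library exceeded the highest FTO library at least 1.22-fold in each tissue. Neither test scaled these counts to the spike-in, and FTO libraries hold fewer spike-in counts than FTOmut libraries. Neither therefore decides on an excess per spike-in count. Genes silent in wild type numbered 27710 in shoot and 26346 in root, of 55801 listed genes. They held at most 0.0544% of gene counts in FTO shoot libraries and 0.746% in FTO root libraries. In wild type they held 0.176 and 0.323% in shoot and 0.239 and 0.243% in root. Genomic DNA would spread counts over silent genes too, so shares this small argue against it as the main source of the excess. A small part from genomic DNA was not ruled out. More RNA per unit of total RNA outside ribosomal RNA in FTO rice may remain, and so could differences in the depletion of ribosomal RNA, which the counts at the chromosome 9 loci could be remnants of, or in the addition of the spike-in, none of which was tested.

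FTOmut replicate 2 detects more genes than any other library of its tissue. Greater depth does not account for it, since after thinning to the smallest library it still detected at least 1.53 times the genes of FTOmut replicate 1. Reads from genomic DNA could give counts in proportion to length at otherwise silent genes: the Spearman correlation with length was 0.389 in root and 0.615 in shoot, where 0.5 in both tissues was set before as the sign and under 0.2 in both as its absence, so genomic DNA cannot be told apart from other sources. No biological explanation was tested, as both replicates share a genotype.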

How the results depend on the processing

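The settings without FTOmut replicate 2 in FTO against wild type, without the 2 chromosome 9 loci, with a peak fold of at least 10, and fry for genes with peaks were chosen only after the result was seen. Among the summary counts and values under alternatives, 126 stayed, 162 moved and 2 changed sign. A count stayed when within 1.5 times the value in the text, and a share of absent peaks when inside its Wilson interval. A difference in peak numbers stayed when its exact permutation p kept its side of 0.05, or its sign without a replicate. A correlation stayed when it differed by under 0.05. Among single named genes, 1098 values kept direction and side of the threshold, 93 lost the call, 59 gained it and 5 changed sign. Causes were not tested except where the setting itself has fewer libraries, tests more genes or shifts all genes. Depth limits these results through n = 2 in each group, and in shoot the test recovered 0% of simulated 2-fold changes and 14% of 4-fold changes. The analyses of peak position and peak motif were not run, and a peak fold of at least 2 removed no peak.

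Scaling by ERCC counts moved genes between FTO and FTOmut root to 11224 and shoot to 1183, repeats to 7380 in FTO against wild-type root and 1275 in FTO against FTOmut root. It turned the direction of 5 uncalled log2 values: OsDCL4 FTO vs FTOmut shoot (LOC_Os04g43050) to 0.0216, OsGI FTO vs WT shoot to 0.0855, OsRDR2 FTO vs WT shoot to 0.170, OsPRR1 FTO vs WT shoot to 0.313 and OsDCL4 FTO vs WT shoot to 0.548. This scaling moves all genes of a comparison alike, the median from -0.16 to 0.60 in FTO against FTOmut shoot and from -0.20 to 0.87 in FTO against wild-type shoot, so the turns are that shift. With DESeq2, shoot genes numbered 31 in FTO against wild type, 394 in FTOmut against wild type and 1181 in FTO against FTOmut, root genes 4195 in FTO against FTOmut, shoot repeats 1 in FTOmut against wild type and 39 in FTO against FTOmut, root repeats 6876 in FTOmut against wild type, and genes whose FTO effect differs between tissues 2691. With no filter, which tests more genes, the same 3 shoot comparisons gave 98, 241 and 1024 genes and 62, 82 and 205 repeats, and root repeats 1153 in FTO against wild type, 6601 in FTOmut against wild type and 327 in FTO against FTOmut. Fits of only the 4 libraries compared gave 3779 genes and 835 repeats in FTO against FTOmut shoot, and 9983 root repeats in FTO against wild type and 243 in FTO against FTOmut. With the factors of the repeat table, FTOmut against wild-type root gave 7929 repeats and 66 families (32 higher, 34 lower), and the root families were 10 in FTO against wild type and 1 in FTO against FTOmut.

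Leaving out 1 library leaves fewer samples and also changes edgeR's filter, which kept 24646 to 35928 shoot genes against 24463, so these moves have more than 1 source. It gave 0 to 3946 shoot genes in FTO against wild type, 0 to 4302 in FTOmut against wild type and 0 to 131 in FTO against FTOmut. In shoot repeats the ranges were 1 to 511, 0 to 506 and 4 to 11802. In root genes they were 4825 to 18234, 12371 to 33822 and 2955 to 17741, and in root repeats 956 to 12071, 1896 to 30359 and 281 to 17229, in the same order. The highest counts of the root repeats came without an FTOmut library, replicate 2 in the first range and replicate 1 in the others. Genes whose FTO effect differs between tissues ranged from 240 to 3259.

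With an estimated correlation, 0 gene lists passed camera in FTO against wild type, FTOmut against wild type and FTO against FTOmut, in root and in shoot. By fry, 5 lists passed in FTO against FTOmut root and 8 in FTOmut against wild-type root, and 0 in FTO against wild-type shoot and FTO against FTOmut shoot. Replicate numbers share only a number: the differences between replicates 1 and 2 correlated between genotypes at 0.02, -0.07 and 0.05 in shoot and -0.05, 0.26 and -0.26 in root. With the replicate block, 2 lists passed in FTO against wild-type shoot and 2 in FTOmut against wild-type shoot. The block gave 12469 genes in FTO against wild-type root, 19905 in FTOmut against wild-type root and 7482 in FTO against FTOmut root.

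For genes with m6A peaks, 0 of the 3 sets passed with an estimated correlation in each comparison. In FTO against wild-type root 1 set passed with a reciprocal overlap of 50%, the genes with a replicated wild-type peak. By fry 1 set passed, the genes with a peak absent from FTO (adjusted p = 0.0182). The replicated set did not pass by fry (adjusted p = 0.174), which tests a set alone and so does not bear on camera's comparison with other genes. In FTOmut against wild-type shoot 0 passed with a reciprocal overlap of 50% and 0 by fry, and in FTO against FTOmut shoot 0 by fry. The correlation of the FTO and FTOmut effects in shoot was -0.221 over genes with a mean log2 CPM of at least 3.

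For peak calls per library, repeat peaks, FTO against the other genotypes, the difference changed sign, to -9.75 at an FDR of at most 0.01, and ran from -231 to 235.25 with single replicates. In shoot, for wild type peaks absent from FTO, wild type peaks absent from FTOmut, FTO peaks absent from wild type, FTO peaks absent from FTOmut, FTOmut peaks absent from wild type, FTOmut peaks absent from FTO, in this order, the shares in percent were 3.04, 3.42, 5.85, 4.86, 5.56 and 4.34 with a reciprocal overlap of 50%, 1.40, 1.57, 3.79, 2.75, 3.40 and 2.44 at a fold of at least 10, and 0.809, 1.27, 2.24, 1.81, 2.13 and 1.69 in genes with at least 10 CPM. Single replicates gave 9.10 to 13.2, 9.75 to 14.7, 15.2 to 20.5, 15.2 to 15.4, 15.4 to 20.0, 14.2 to 14.3. In root, for wild type peaks absent from FTO, wild type peaks absent from FTOmut, FTO peaks absent from wild type, FTO peaks absent from FTOmut, FTOmut peaks absent from wild type, FTOmut peaks absent from FTO, in this order, the shares in percent were 3.66, 5.97, 5.31, 4.99, 7.36 and 4.70 with a reciprocal overlap of 50%, 2.07, 3.85, 3.38, 2.84, 5.29 and 2.84 at a fold of at least 10, and 1.33, 3.14, 1.94, 2.44, 2.75 and 1.47 in genes with at least 10 CPM. Single replicates gave 11.1 to 19.2, 14.4 to 17.7, 16.3 to 22.0, 13.96 to 21.5, 18.5 to 18.7, 15.0 to 17.8. Single replicates also hold peaks that their partner lacks, which raises these shares.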

Other observations

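No test in this part was chosen only after the result was seen, but the repeat family and the HygR peak were singled out after their values were seen.

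Beyond the groups described above, phosphate starvation genes went both ways in FTO root, with 1 of 6 higher and 1 lower, OsPT2 (camera adjusted p = 0.759; fry's adjusted p for changes either way 0.000648), while in FTOmut root 3 of 6 were lower, including OsSPX2 (LOC_Os02g10780) at -1.23 and OsSPX1 (LOC_Os06g40120) at -0.93, regulators of the phosphate response. Of 8 nitrogen uptake and assimilation genes, 1 was higher and 2 were lower in FTO root (adjusted p = 0.236), and 3 were higher and 2 lower in FTOmut root (adjusted p = 0.932). Root marker genes were lower in 3 of 9 cases in FTO root (adjusted p = 0.0642) and in FTOmut root 3 were lower and 1 higher (adjusted p = 0.437). Of 4 defence genes 1 was higher in FTO root, and in FTOmut root 1 was higher and 2 were lower. The auxin transporter gene OsPIN1b (LOC_Os02g50960) was lower in FTOmut root at -1.62 (SE 0.24). Neither of the 2 m6A machinery genes was called over all genes in any comparison, and 1 passed in FTO root adjusted over the list alone. Neither of the 2 auxin genes was called in FTO root. Of 3 histone lysine methylation genes 1 was lower in FTO root, the heat shock and cytokinin lists had 1 member each, not called over all genes in any comparison, and of 3 gibberellin genes 1 was higher in FTO root and 1 lower in FTOmut root.

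In shoot, the list of abscisic acid, drought and LEA genes had a median log2 fold change of -1.60 in FTO against wild type while camera's direction was upward (adjusted p = 0.695), with OsDREB1A at -1.60 and OsLEA3 at 2.42. Adjusted over the list alone, 4 of its 5 members passed in FTO against FTOmut shoot. The 10307 tested genes with a replicated wild-type peak moved up in FTO against FTOmut shoot (camera adjusted p = 0.0263; 0.184 with an estimated correlation), with a median of 0.04 against 0.03 in random sets. The 168 genes with a wild-type peak absent from FTO moved down there (median -0.85 against -0.36 in random sets, adjusted p = 0.00381; 0.549 with an estimated correlation) and up in FTOmut against wild-type shoot (adjusted p = 0.00614; 0.564 with an estimated correlation). This set is partly chosen by the level in FTO, since finding a peak takes reads, and the share of wild-type peaks absent fell from 2.30 to 0.809% in genes with at least 10 CPM, so its moves do not tell an effect of m6A.

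The repeat family test in shoot called 1 of 190 families in FTOmut against wild type (FTOmut vs WT shoot), ORSgRGRR, which was lower at -1.72 (SE 0.24, edgeR adjusted p = 0.0291). The gene peak list of wild-type shoot replicate 2 holds a peak named HygR, which is a name of hygromycin resistance, on a sequence named ChrI from position 397 to 516 with a fold of 4.0 over input. No other list of gene peaks holds a name outside the rice loci, those of FTO and FTOmut rice included, so this peak does not follow the transgenic labels. A resistance marker goes against the label of a wild-type list, and the RNA-seq library of the same number stands apart in shoot. Those are separate libraries, and whether this sample holds transgenic material stays open for every shoot comparison with wild type.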
